A study of Rattus norvegicus with 44 samples.

How the data were processed

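The series holds 44 arrays of total RNA, extracted with TRI Reagent per the labels' protocols, 27 from liver and 17 from kidney of male Harlan Sprague Dawley rats that were 6 to 8 weeks old when assigned to groups. Rats received MCHM in corn oil by gavage for 5 days at a volume of 5 mL/kg. The array is an Affymetrix rat expression array with 3' probe sets. Arrays with batch effects were removed before deposit, per the series' design text, and were not used here, which left 3 or 4 vehicle arrays and 2 to 4 arrays at each dose. The labels call the samples of a group biological replicates. Each array was put in its group through its title. A kidney array at 10 mg/kg has no replicate number in its title, so it was numbered in accession order and left out of fits that use the number.

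The deposited table holds log2 expression values summarised by RMA (background correction, quantile normalization and median polish of probes into probe sets), per the submitters' processing notes. The version of RMA, the software and the chip definition are not given in the sources used here, nor is whether liver and kidney were normalized together. Quantile normalization gives the arrays of a set near-identical distributions, so a shift of most transcripts in 1 direction would not be seen, and RMA compresses changes of dim probe sets. The values run from 1.80 to 14.85, and 0 pairs of arrays held identical values. No scanner files were used here, so no probe set could be called above or below background.

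The table holds 31099 probe sets. After 57 control probe sets were left out, 31042 were tested. Of these 20826 have 1 gene symbol, 436 have several and 9780 have none in the platform annotation. Symbols were updated through the gene ID with a table of rat genes from assembly GRCr8, used for names only, in which 20758 matched, and 14217 different genes are named. No gene is named from a probe set with several symbols, and a gene stands for its probe set with the highest mean in the organ. *Cyp2b1* is not analysed here, and some other genes are not reported here. No genome was used, so no positions are given.

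From these values limma 3.58.1 in R 4.3.3 fitted each organ's 7 dose groups together with lmFit and eBayes, so that all groups share 1 estimate of the spread. Each dose was compared with the vehicle group of the same organ, a slope was fitted over the dose levels 0 to 6, and the liver change minus the kidney change at 300 and 500 mg/kg was tested in 1 fit of all arrays. That fit holds no animal block, because the labels do not say that liver and kidney arrays share animals. If they do, its standard errors and its splits do not account for it. Tests were two-sided, with Benjamini-Hochberg adjustment over the 31042 probe sets of a comparison and a threshold of 0.05. Every adjusted p in the text is from limma. These fits, the named genes, the gene lists, and the alternatives listed first in a later paragraph were chosen before the data were examined.

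The genes named are, at 500 mg/kg in each organ, the 6 that rose and the 6 that fell most among those past the threshold with no overlap between groups, and the 4 each way at 300 and at 100 mg/kg. At 0.1, 1 and 10 mg/kg they are all genes past the threshold if there are 5 or fewer, and otherwise 3 each way. They further include up to 2 members per list at 500 mg/kg with the smallest p past the threshold, the 4 each way with the smallest p in the trend and the 4 each way in the organ difference at 500 mg/kg, where fewer passed. *Cyp1a1*, *Cyp3a23-3a1*, *Cyp4a1*, *Cyp7a1*, *Cyp2c11*, *Nqo1*, *Cdkn1a*, *Adh1c*, *Aldh1a1*, *Havcr1* and *Lcn2* are given whatever their values. Cell type markers are given as list medians, with members only where they passed.

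For 20 gene lists, limma's camera with a preset correlation of 0.01 compared the members with all other genes at 100, 300 and 500 mg/kg, adjusted over the lists of a comparison. Measured members numbered 21 for CAR and PXR targets, 7 for aryl hydrocarbon receptor targets, 25 for NRF2 targets, 37 for PPARA targets, 21 for cholesterol synthesis, 20 for fatty acid synthesis, 19 for bile acid genes and 14 for glucose metabolism. They numbered 22 for amino acid metabolism, 18 for alcohol and aldehyde oxidation, 16 for male-biased liver genes, 24 for the unfolded protein response, 10 for heat shock, 16 for p53 targets, and 36 for cell cycle. They numbered 22 for acute phase, 22 for kidney injury, 21 for proximal tubule, 16 for circadian clock and 24 for oxidative phosphorylation. A further 14 lists hold cell type markers, and a list needed at least 3 measured members. Older symbols of list members were matched through synonyms, a step added after list results had been seen. It added *Adh1c* under its older name, and with it the alcohol and aldehyde list passed the threshold at 500 mg/kg in liver.

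The alternatives set beforehand were fits of only the probe sets whose mean lies above the median of all, a second quantile normalization within the organ, 1 probe set per gene before the fit, and eBayes with trend and robust options. They were also array weights, the replicate number as a block, a fit of only the groups compared, dose in mg/kg as a number for the trend, each array left out in turn, camera with an estimated correlation, fry, and the mean of a gene's probe sets in list tests. Alternatives added after the data were seen were an adipose marker covariate, a GAPDH 3' minus 5' covariate, kidney fits without 2 doubtful arrays, kidney fits without vehicle replicate 1 and with the adipose covariate, and the 500 mg/kg kidney fit with only vehicle replicate 1. So were lists with each array left out, the direct comparison of 300 with 500 mg/kg, and pooled low doses as the reference. Comparisons of at least 3 arrays per group were repeated over all splits of their arrays into groups of the same sizes, or over 100 splits drawn with a fixed seed.

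The fits were tested on simulated data in which 200 of the 31042 probe sets were changed. Of changes of 1 log2 unit, 97.0% were recovered for liver at 500 mg/kg, 98.5% for liver at 300 mg/kg, 83.6% for kidney at 500 mg/kg, 97.0% for kidney at 300 mg/kg and 77.6% for the organ difference at 500 mg/kg. Of changes of 0.5, the shares were 47.8%, 53.7%, 43.3%, 38.8% and 17.9%. In the trends, 97.0% of changes of 1 were recovered in liver and 94.0% in kidney. A list of 30 shifted genes had a camera p of 9.1e-26 in these simulated data and an unchanged list of 30 one of 0.464. The simulated noise was drawn independently for each probe set. It therefore does not test lists whose members vary together, such as cholesterol synthesis in liver, with an estimated correlation of 0.59. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, from tables read with pandas 2.3.3.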

Results

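Gene expression was measured in liver and kidney of male Harlan Sprague Dawley rats given crude 4-methylcyclohexanemethanol (MCHM), an industrial alcohol mixture used to wash coal, by gavage in corn oil on 5 days. Rats received vehicle alone (0 mg/kg) or 500, 300, 100, 10, 1 or 0.1 mg/kg of MCHM, and tissue was taken on the day after dosing ended. The liver arrays numbered 27, with 4 at each dose except 3 at 0.1 mg/kg. The kidney arrays numbered 17, with 3 at 0, 300 and 500 mg/kg and 2 at each of the other doses. The number of arrays limits the precision of every comparison. Across probe sets, pairs of liver arrays correlated at r = 0.989 to 0.994 and pairs of kidney arrays at 0.984 to 0.996. Probe sets are not independent replicates. Changes are log2 differences between group means, a fall carries a minus sign, and SE is the standard error from limma.

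*Xist*, the RNA that coats an inactivated X chromosome and is a mark of a second X, read 11.00 in liver vehicle replicate 2 and 9.33 in kidney vehicle replicate 2. It lay between 2.29 and 3.04 in the other liver arrays and between 2.21 and 2.59 in the other kidney arrays. The gene lies outside the rule for named genes and was chosen after its values were seen. The Y-linked *Eif2s3y* read 9.26 in that liver array, between 8.94 and 9.49 in the other liver arrays, 10.02 in that kidney array and between 9.35 and 9.94 in the other kidney arrays.

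**Figure D1:**
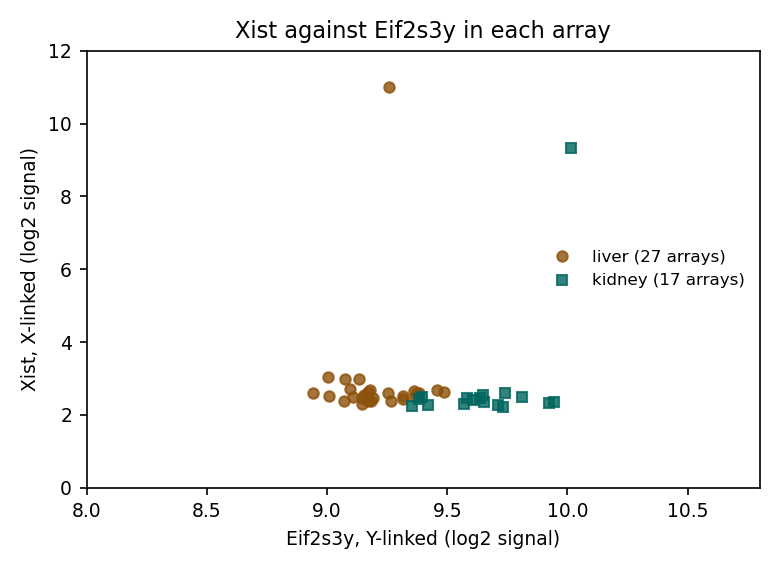
Log2 expression of *Xist* (vertical axis) against the Y-linked *Eif2s3y* (horizontal axis) in all 44 arrays, with 1 point per array. The *Xist* values of 11.00 in liver and 9.33 in kidney belong to vehicle replicate 2 of each organ.

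The comparison of 500 mg/kg with vehicle asks which liver transcripts differ at the top dose. *Cyp3a9*, a cytochrome P450 of steroid and drug oxidation, rose by 1.75 (SE 0.32, 4 arrays per group, adjusted p = 0.0224), or 3.36-fold, from 7.82 ± 0.54 (SD, n = 4) to 9.57 ± 0.23. The enoyl-CoA isomerase *Eci1* rose by 0.87 (SE 0.11, adjusted p = 3.14e-04). The fatty acid omega-hydroxylase *Cyp4a1* rose by 0.79 (SE 0.15, adjusted p = 0.0249) and the peroxisomal bifunctional enzyme *Ehhadh* by 0.74 (SE 0.13, adjusted p = 0.0126). The plasma proteinase inhibitor gene *A2m* changed by −1.54 (SE 0.27, adjusted p = 0.0153), from 10.12 ± 0.50 to 8.58 ± 0.30. *Serpina7*, which encodes thyroxine-binding globulin, changed by −1.46 (SE 0.23, adjusted p = 0.00569), from 10.14 ± 0.32 to 8.68 ± 0.35. For each of these genes all 4 dosed livers lay beyond all 4 vehicle livers, a separation that the naming rule asks of most of them and that adds no evidence. The dimmer second probe set of *Eci1* had the opposite sign and did not pass the threshold.

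Among the other named genes past the threshold at 500 mg/kg in liver, *Abhd1*, a gene of the alpha/beta hydrolase family, rose by 0.76 (SE 0.09, adjusted p = 1.43e-04). The alanine aminotransferase gene *Gpt* rose by 1.05 (adjusted p = 0.0366) and the carboxylesterase *Ces2c* by 0.85 (0.0306). *Cyp3a23-3a1* rose by 0.65 (0.0306), *Cyp3a18* by 0.55 (0.0291), biliverdin reductase *Blvrb* by 0.55 (0.00916) and the sterol reductase *Tm7sf2* by 0.51 (0.0364). *Fabp7*, a fatty acid binding protein, changed by −0.72 (SE 0.09, adjusted p = 3.61e-04). *Tmbim7* changed by −1.13 (0.0163), the immunoglobulin joining chain *Jchain* by −0.81 (0.0473) and the uncharacterised *LOC102556004* by −0.57 (0.0366). Genes watched in advance that did not pass were *Cyp7a1*, the rate-limiting enzyme of bile acid synthesis (1.13, SE 0.46, adjusted p = 0.453), *Nqo1* (0.57, 0.270) and *Adh1c* (0.43, 0.261). *Cyp1a1* (0.33, 0.60), *Cyp2c11* (0.16, 0.573), *Cdkn1a* (0.12, 0.877), *Aldh1a1* (0.04, 0.970), *Havcr1* (−0.11, 0.920) and *Lcn2* (−0.01, 0.999) did not pass either. In all, 55 of 31042 probe sets passed the threshold at 500 mg/kg, 37 higher and 18 lower. A fit of only these 2 groups, which estimates the spread from fewer arrays, called 1 probe set and 0 of the 17 named genes. A second quantile normalization called 51 and lost *Gpt*, *Jchain* and *Tm7sf2*, and the replicate block lost *Jchain*, *LOC102556004*, *Tm7sf2* and *Cyp3a23-3a1*. At an unadjusted p under 0.05 there were 2792, where chance alone gives 1552.1. The count was 84 without vehicle replicate 1, 14 without replicate 2, 9 without replicate 3 and 11 without replicate 4. It was 17, 19 and 13 without 500 mg/kg replicates 1, 3 and 4. *Eci1*, *Abhd1*, *Fabp7* and *Serpina7* passed in each of the 8 fits that left out 1 array of either group. *Blvrb* was lost only without vehicle replicate 4 and *Tmbim7* only without vehicle replicate 3 and 500 mg/kg replicate 4. Of the 17 named genes, 16, 6, 5 and 5 passed without vehicle replicates 1 to 4 in turn, and 7, 12, 9 and 6 without 500 mg/kg replicates 1 to 4 in turn.

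**Figure D2:**
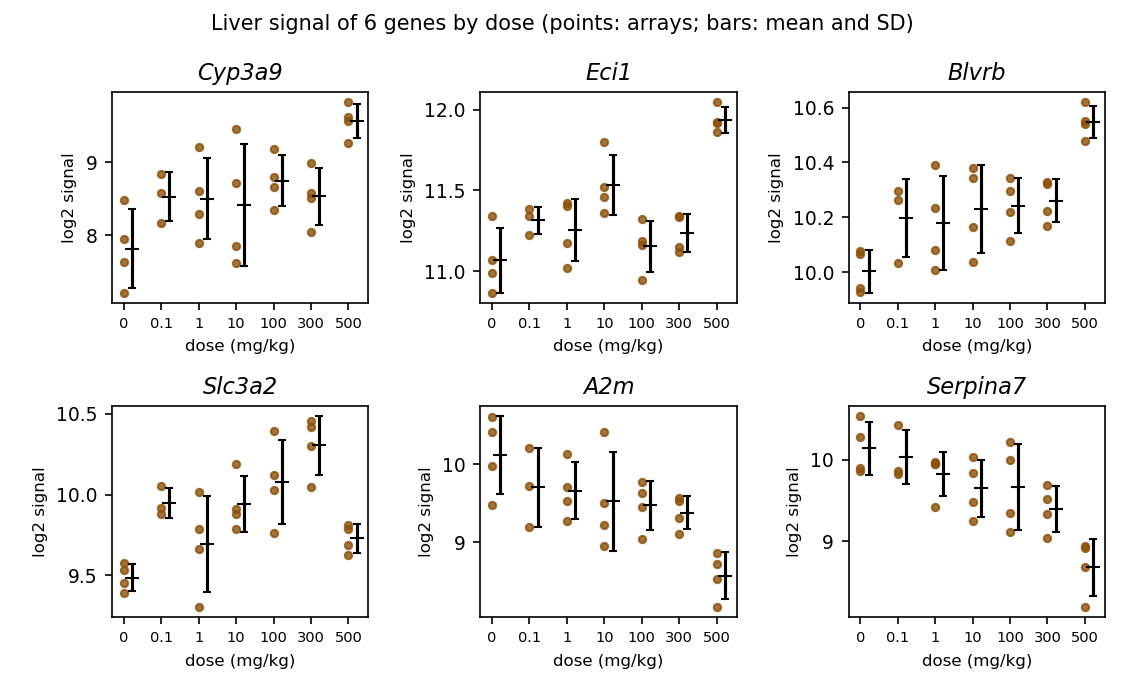
Log2 expression of *Cyp3a9*, *Eci1*, *Blvrb*, *Slc3a2*, *A2m* and *Serpina7* in every liver array by dose in mg/kg; points are arrays and bars show the group mean and SD. *Serpina7* has a mean of 10.14 in vehicle livers and 8.68 at 500 mg/kg, while the mean of *Slc3a2* is 9.48 in vehicle livers and 10.30 at 300 mg/kg.

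Among lists of genes fixed in advance, genes induced through the nuclear receptors CAR and PXR had 4 of 21 measured members past the threshold over all probe sets at 500 mg/kg in liver, namely *Cyp3a9*, *Ces2c*, *Cyp3a18* and *Cyp3a23-3a1*. Adjusted over the list alone, 6 members were higher and 1, the transporter *Slco1a4* (−0.31), was lower. The list's median was 0.14 (limma's camera adjusted p = 5.31e-05; adjusted p = 0.122 with an estimated correlation). Targets of the fatty acid receptor PPARA had 4 of 37 members past the threshold, *Eci1*, *Ehhadh*, *Cyp4a1* and *Decr2* (0.43). Adjusted over the list alone 7 were higher and 1, the glycerol channel *Aqp7* (−0.63), was lower. The median was 0.11 (camera adjusted p = 2.35e-05; adjusted p = 0.123 with an estimated correlation). Targets of the antioxidant regulator NRF2 had 1 of 25 members past the threshold, *Blvrb*, and 9 higher adjusted over the list alone. The list's median was 0.17 (camera adjusted p = 3.32e-06; adjusted p = 0.123 with an estimated correlation). The glutathione transferase *Gsta3* (1.19), the glutamate-cysteine ligase subunit *Gclc* (0.39) and the thioredoxin reductase *Txnrd1* (0.34) were among those 9. List members outside the rule for named genes, here and in the later paragraphs, are examples that were chosen after their values were seen.

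Cholesterol synthesis genes had 1 of 21 members past the threshold at 500 mg/kg, *Tm7sf2*, and 4 higher adjusted over the list alone, the others being *Dhcr7* (0.53), *Pmvk* (0.41) and *Ebp* (0.37). The list's median was 0.12 (camera adjusted p = 5.36e-04; adjusted p = 0.386 with an estimated correlation). Fatty acid synthesis genes had 0 of 20 members past limma's threshold and 1 adjusted over the list alone, the lipogenic regulator *Thrsp* (0.98). Their median was 0.21 (camera adjusted p = 5.36e-04; adjusted p = 0.248 with an estimated correlation). Heat shock genes had 0 of 10 past the threshold and 3 adjusted over the list alone, *Hspa4l* (0.59) and the mitochondrial chaperones *Hspe1* (0.31) and *Hspd1* (0.19). The heat shock median was 0.25 (camera adjusted p = 2.35e-05; adjusted p = 0.122 with an estimated correlation). Oxidative phosphorylation genes had 22 of 24 members above vehicle and 0 past the threshold or adjusted over the list alone. Their median of 0.12 was called (camera adjusted p = 1.09e-06; adjusted p = 0.173 with an estimated correlation). Genes of alcohol and aldehyde oxidation had 0 of 18 past the threshold and 2 adjusted over the list alone, *Adh1c* and the ethanol-oxidising P450 *Cyp2e1* (0.25). Their median was 0.10 (camera adjusted p = 0.0266; adjusted p = 0.275 with an estimated correlation). The call was lost without vehicle replicate 4 or 500 mg/kg replicate 1 (adjusted p up to 0.180).

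Acute phase genes had 1 of 22 members past the threshold at 500 mg/kg, *A2m*. Adjusted over the list alone *A2m* was lower and *Orm1* (0.56), another plasma protein gene, was higher. The list had a median of −0.05 (camera adjusted p = 0.0406; adjusted p = 0.248 with an estimated correlation). Its call was lost without vehicle replicate 2 and without each 500 mg/kg array (adjusted p up to 0.153). Genes of kidney injury, which include the mesenchymal *Vim* (−0.31) and the adhesion molecule *Vcam1* (−0.31), had 0 of 22 members past the threshold or adjusted over the list alone in liver. Their median was −0.12 (camera adjusted p = 0.00270; adjusted p = 0.218 with an estimated correlation; 0.0646 without vehicle replicate 2). The other lists were not called, with camera adjusted p of 0.0885 for aryl hydrocarbon receptor targets, 0.131 for p53 targets, 0.224 for proximal tubule, and 0.231 for amino acid metabolism. It was 0.270 for bile acid genes, 0.285 for circadian clock, 0.286 for cell cycle, 0.522 for male-biased liver genes, 0.929 for the unfolded protein response and 0.947 for glucose metabolism. The glucose list's median, mean and test differed in sign. No cell type marker passed the threshold in liver at 500 mg/kg. Marker medians were −0.27 for stellate cells and fibroblasts (3 of 10 lower adjusted over the list alone), −0.25 for cholangiocytes, −0.18 for macrophages and −0.15 for endothelium. They were −0.14 for lymphocytes and −0.03 for hepatocytes. They lay between −0.03 and 0.05 for the remaining lists.

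At 300 mg/kg in liver *Slc3a2*, the heavy chain shared by several amino acid exchangers, rose by 0.82 (SE 0.13, 4 arrays per group, adjusted p = 0.0104), from 9.48 ± 0.08 to 10.30 ± 0.18 (SD, n = 4). The isoleucyl-tRNA synthetase *Iars1* rose by 0.71 (SE 0.12, adjusted p = 0.0114). The cationic amino acid transporter *Slc7a1* rose by 0.83 (SE 0.17, adjusted p = 0.0438) and the deubiquitinase *Otub2* by 1.42 (SE 0.22, adjusted p = 0.00940). At 0.1, 1, 10 and 100 mg/kg *Slc3a2* differed from vehicle by 0.46, 0.21, 0.45 and 0.59 and *Slc7a1* by 0.66, 0.32, 0.50 and 0.64, none past the threshold. Against the pooled arrays at 0.1, 1 and 10 mg/kg, a comparison chosen after the values were seen, the difference at 300 mg/kg was 0.45 for *Slc3a2* and 0.35 for *Slc7a1*. The kinase gene *Nim1k* changed by −1.96 (SE 0.30, adjusted p = 0.00940), from 7.36 ± 0.34 to 5.40 ± 0.61. The calcium channel subunit *Cacna1d* changed by −0.65 (0.0476), *Spin4* by −0.56 (0.0482) and *Fabp7* by −0.49 (0.0328). For each named gene all 4 dosed arrays lay beyond all 4 vehicle arrays, as the naming rule requires. A dim second probe set of *Iars1* had the opposite sign, and 1 of the 2 further probe sets of *Slc7a1* and of *Cacna1d* had the same sign as the one reported.

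In all, 38 probe sets passed the threshold at 300 mg/kg in liver, 33 higher and 5 lower, with 3050 at an unadjusted p under 0.05. A fit of only these 2 groups called 2 probe sets and 1 of the 8 named genes, *Otub2*. A second quantile normalization called 16, of which 75.0% were higher in place of 86.8%, and lost *Slc7a1*, *Cacna1d* and *Spin4*. The replicate block lost *Cacna1d*. *Spats2* (−0.52, adjusted p = 0.0328), 1 of the 5 lower probe sets, lies outside the rule for named genes and was chosen after its values were seen. The count was 16, 0, 16 and 22 without vehicle replicates 1 to 4 in turn (replicate 2, without which it was 0, is the array with *Xist*), and 11, 18, 3 and 17 without 300 mg/kg replicates 1 to 4 in turn. Of the 8 named genes 6, 0, 4 and 4 passed in the first set of fits and 4, 6, 2 and 4 in the second. Fatty acid synthesis genes had 19 of 20 members above vehicle, 0 past limma's threshold over all probe sets and 12 adjusted over the list alone. Their median was 0.59 (camera adjusted p = 2.87e-10; adjusted p = 0.180 with an estimated correlation). Examples are the elongase *Elovl6* (1.15), the lipogenic transcription factor *Srebf1* (0.90), fatty acid synthase *Fasn* (0.78) and acetyl-CoA carboxylase *Acaca* (0.58). A dimmer probe set of the member *Pklr* passed limma's threshold over all probe sets (0.80, adjusted p = 0.0328). The brighter one that stands for the gene did not (0.50, adjusted p = 0.132). The circadian clock list, with 1 of 16 members above vehicle and a median of −0.14, was not called (camera adjusted p = 0.0783). With fry it passed (adjusted p = 0.0132), and with an estimated correlation it did not (camera adjusted p = 0.180). NRF2 targets had 1 of 25 past the threshold, sulfiredoxin *Srxn1* (0.58), and 6 adjusted over the list alone. Their median was 0.13 (camera adjusted p = 4.04e-04; adjusted p = 0.404 with an estimated correlation). Cholesterol synthesis genes had 1 of 21 past the threshold, *Tm7sf2*, and 2 adjusted over the list alone, the other being *Ebp* (0.40). Their median was 0.15 (camera adjusted p = 0.00165; adjusted p = 0.552 with an estimated correlation; 0.0646 without vehicle replicate 4). The stress-response genes *Asns* (1.36) and *Trib3* (1.41) passed adjusted over the unfolded protein response list alone, while that list was not called. For this list and for glucose metabolism, the median, mean and test differed in sign at 300 mg/kg. *Asns* read 6.75 to 7.97 in vehicle livers and 8.44 to 9.04 at 300 mg/kg. At lower doses it read 7.84 to 8.47 at 0.1 mg/kg, 6.34 to 7.92 at 1 mg/kg, 7.61 to 8.62 at 10 mg/kg and 7.59 to 8.46 at 100 mg/kg. No cell type marker passed the threshold, and the stellate cell and fibroblast median was −0.35 (4 of 10 lower adjusted over the list alone).

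At 0.1, 1, 10 and 100 mg/kg limma called 0 probe sets in liver, with 1582, 1565, 1724 and 1872 at an unadjusted p under 0.05. The means of *Fabp7* were 11.91, 11.96, 11.87 and 11.78 at these doses beside 12.16 in vehicle livers, and those of *Serpina7* were 10.03, 9.82, 9.65 and 9.67 beside 10.14. Cell cycle genes had a median of −0.23 at 100 mg/kg, with 0 of 36 past the threshold or adjusted over the list alone (camera adjusted p = 3.53e-05; adjusted p = 0.877 with an estimated correlation). Examples are the mitotic kinases *Bub1b* (−0.35) and *Aurkb* (−0.45). The call was lost without vehicle replicate 4 (adjusted p = 0.152). Without vehicle replicate 4, 1 probe set was called at 0.1 and at 10 mg/kg, and without 100 mg/kg replicate 1, 2 were called at 100 mg/kg.

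The trend over the 7 dose levels, coded 0 to 6, asks which liver transcripts move steadily with dose. *Fabp7* changed by −0.10 per level (SE 0.01, 27 arrays, adjusted p = 2.50e-04) and *Serpina7* by −0.21 (SE 0.03, adjusted p = 0.00445), with group means of 11.67 and 9.40 at 300 mg/kg and 11.44 and 8.68 at 500 mg/kg. The peroxiredoxin *Prdx4* changed by −0.05 and the chemokine *Ccl5* by −0.09 per level (adjusted p = 0.0193 for each). *Abhd1* rose by 0.10 per level (SE 0.01, adjusted p = 0.00195), from 8.04 in vehicle livers over 8.33 at 100 mg/kg to 8.80 at 500 mg/kg. *Tmem97*, a sterol-regulated membrane protein gene, rose by 0.08 per level (adjusted p = 0.00195), *Tm7sf2* by 0.11 (0.00559) and the iron-binding *Pir* by 0.09 (0.0163). The trend called 76 probe sets, 52 rising and 24 falling, with 3484 at an unadjusted p under 0.05. All 8 named genes passed in every fit without 1 array except *Prdx4* and *Ccl5* without 500 mg/kg replicate 4. The count was 12 without that array, 38 and 30 without 500 mg/kg replicates 1 and 3, 44 and 39 without 300 mg/kg replicates 1 and 4, and 45 and 44 without vehicle replicates 2 and 3.

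**Figure D3:**
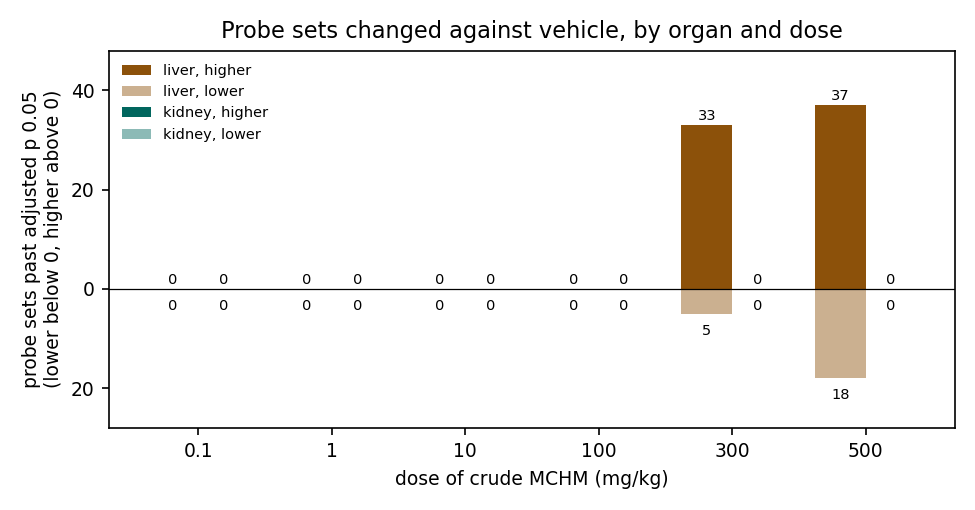
Probe sets past the adjusted threshold against vehicle in liver and kidney by dose in mg/kg, with higher ones above zero and lower ones under it. Liver has 38 at 300 mg/kg and 55 at 500 mg/kg, and every other comparison has 0.

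In kidney no gene passed the threshold at any dose. *Cyp4a1* differed by 0.00 at 500 mg/kg (SE 0.16, 3 arrays per group, adjusted p = 0.997), with means of 10.34 in both groups. The kidney injury markers *Havcr1* (−0.06, SE 0.29, adjusted p = 0.966) and *Lcn2* (0.17, SE 0.25, adjusted p = 0.864) did not pass. Neither did *Cyp1a1* (0.51, 0.877), *Cdkn1a* (−0.37, 0.639), *Nqo1* (0.10, 0.889), *Aldh1a1* (−0.20, 0.608), *Adh1c* (−0.17, 0.826), *Cyp2c11* (−0.33, 0.895), *Cyp3a23-3a1* (−0.33, 0.811) or *Cyp7a1* (−0.37, 0.639). In rising order of the 6 doses limma called 0 probe sets at each, with 1832, 2168, 1522, 1225, 1123 and 3131 at an unadjusted p under 0.05. The smallest adjusted p at 500 mg/kg was 0.326. The kidney trend called 0, with 2205 at an unadjusted p under 0.05. Without vehicle replicate 1 the counts were 319, 201, 138, 23, 103 and 616 in the same order of doses, and 289 of the 319, 187 of the 201, 131 of the 138, 23 of the 23 and 102 of the 103 were also called at 500 mg/kg against the same pair of vehicle arrays. With all vehicle arrays they were 7 and 58 at 1 mg/kg without replicate 1 or 2 of that dose, and 1 at 10 mg/kg without replicate 1 of that dose.

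Kidney vehicle replicates 2 and 3 stood apart from replicate 1 and most other kidney arrays. On the first principal component of the kidney arrays (24.3% of the variance) they lay at 35.3 and 25.3 and 300 mg/kg replicate 2 at 39.6, while vehicle replicate 1 lay at −13.0 and the rest between −24.0 and 15.7. The translation factor *Eif3a* read 4.96 and 4.93 in replicates 2 and 3, 7.61 in replicate 1 and between 6.30 and 7.82 in all dosed kidneys. The chromatin remodeller *Atrx* read 4.26 and 4.82 against 6.29, and between 5.40 and 6.80 in dosed kidneys. The splicing factor *Scaf11* read 4.72 and 5.15 against 7.27, and between 6.30 and 7.76 in dosed kidneys. For *Atrx*, *Scaf11* and *Eif3a* the means at 500 mg/kg were 6.58 ± 0.10, 7.56 ± 0.19 and 7.67 ± 0.11 (SD, n = 3). These 3 genes were chosen after their values were seen. The difference between the 3' and 5' GAPDH control probe sets, which grows as RNA degrades, was 2.00 in 300 mg/kg replicate 2. The next highest kidney values were 0.60 and 0.57, in vehicle replicates 3 and 2, beside 0.31 in vehicle replicate 1. For beta-actin the difference was 3.88 in 300 mg/kg replicate 2. It was 2.82 and 2.68 in vehicle replicates 3 and 2, and 2.17 in vehicle replicate 1. The liver transcript *Alb* read 11.06 in 1 mg/kg replicate 1 and at most 5.86 elsewhere. The brown fat gene *Ucp1* read 11.47 in 1 mg/kg replicate 2, 9.86 in 300 mg/kg replicate 2 and in 500 mg/kg replicate 2, and 9.17 in vehicle replicate 3, beside a kidney median of 4.76.

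**Figure D4:**
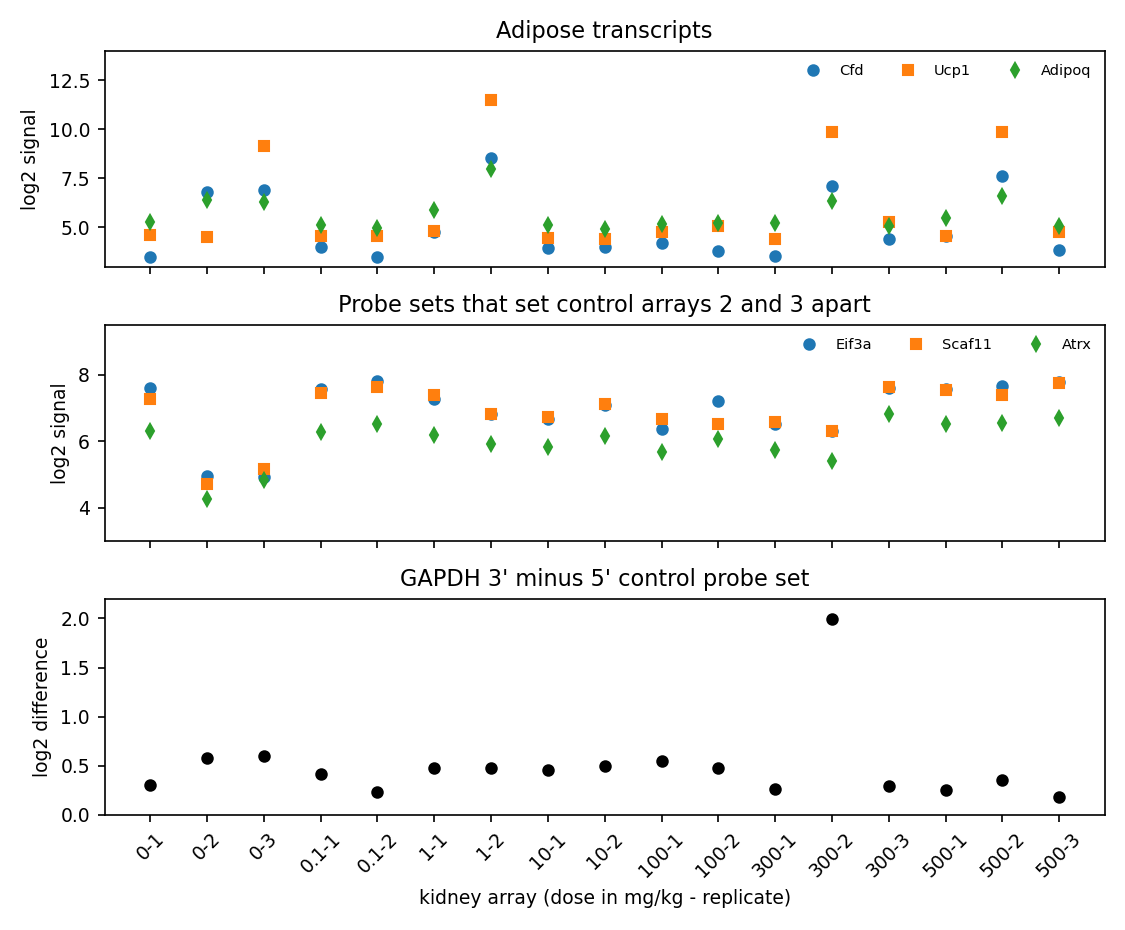
Log2 expression in every kidney array by dose in mg/kg of the fat genes *Cfd*, *Ucp1* and *Adipoq*, of *Eif3a*, *Scaf11* and *Atrx*, and the 3' minus 5' difference of the GAPDH control probe sets; points are arrays. *Eif3a* reads 7.61, 4.96 and 4.93 in the 3 vehicle kidneys, and the GAPDH difference of 300 mg/kg replicate 2 is 2.00.

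Cholesterol synthesis genes were higher as a list in kidney, with 0 of 21 members past limma's threshold or adjusted over the list alone at 300 mg/kg. The median there was 0.13 (camera adjusted p = 4.52e-06; adjusted p = 0.544 with an estimated correlation). At 500 mg/kg the median was 0.11 (camera adjusted p = 1.18e-04; adjusted p = 0.682 with an estimated correlation). The sterol sensor *Insig1* (0.33) was the 1 of 21 members that passed adjusted over the list alone, beside *Cyp51* (0.36) and *Sc5d* (0.30). Unfolded protein response genes had 0 of 24 members past the threshold or adjusted over the list alone at 300 mg/kg. Their median was −0.16 (camera adjusted p = 5.09e-05; adjusted p = 0.544 with an estimated correlation). The phosphatase subunit *Ppp1r15a* differed by −0.47 and the chaperone *Dnajb9* by −0.30. PPARA targets had 0 of 37 members past the threshold or adjusted over the list alone at 500 mg/kg. Their median was 0.02 (camera adjusted p = 0.0205; adjusted p = 0.682 with an estimated correlation). *Eci1* differed by 0.46 and *Cyp4a3* by 0.34. That call was lost without vehicle replicate 2 or 3 or 500 mg/kg replicate 1 (adjusted p up to 0.267). No list was called at 100 mg/kg. At 500 mg/kg the median, mean and test differed in sign for the CAR and PXR, NRF2, fatty acid synthesis, alcohol and aldehyde, acute phase and kidney injury lists. No cell type marker passed the threshold at 500 mg/kg, where the macrophage median was −0.37 (6 of 10 lower adjusted over the list alone), the endothelial median −0.26 (1 of 8), the glomerular median −0.24 and the thick ascending limb median 0.51.

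The liver change minus the kidney change asks whether the organs responded differently. Its fit treats liver and kidney arrays as independent, and whether they share animals is not known. At 500 mg/kg it was 1.12 for *Ccdc85c* (SE 0.21, adjusted p = 0.0299), 1.05 for the transcriptional regulator *Hes6* (SE 0.18, adjusted p = 0.0116) and 1.04 for the transporter *Slc16a13* (SE 0.20, adjusted p = 0.0316). It was −1.55 for the transcription factor *Trps1* (SE 0.30, adjusted p = 0.0350), from 4 arrays per liver group and 3 per kidney group. *Hes6* differed by 0.44 in liver and −0.61 in kidney, and *Trps1* by −0.68 in liver and 0.87 in kidney, where it read 8.93, 8.21 and 8.33 in vehicle replicates 1 to 3. With the replicate number as a block, *Ccdc85c*, *Slc16a13* and *Trps1* lost their calls and *Hes6* kept its own. Without a block 9 probe sets passed at 500 mg/kg, 3 higher and 6 lower, with 3075 at an unadjusted p under 0.05. The count was 746, 0 and 2 without kidney vehicle replicates 1 to 3 in turn, and 24, 3 and 4 without kidney 500 mg/kg replicates 1 to 3. It was 5, 2 and 5 without liver vehicle replicates 2 to 4, and 4 and 3 without liver 500 mg/kg replicates 2 and 4. At 300 mg/kg limma called 0, with 1961 at an unadjusted p under 0.05. That count was 200 without kidney vehicle replicate 1, 3 and 2 without kidney 300 mg/kg replicates 1 and 2, and 1 each without liver vehicle replicate 1 or 4 or liver 300 mg/kg replicate 2.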

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

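The *Xist* tests of sex, admixture and pairing and the matching of organs were chosen after the values were seen, and the bound on the pairing test was set after its value was known (without it the value would count for different animals). The test on genes that escape X inactivation was written beforehand.

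*Xist* lay far from the other vehicle livers in vehicle replicate 2, at 11.00 beside 2.38 to 2.66, and kidney vehicle replicate 2 read 9.33. A female animal or a swap with one would leave *Eif2s3y* low, but it lay 0.0823 above the median of the other livers, and higher in kidney. That argues against both as far as its 1 probe set reads only the Y-linked gene. All rats are labelled male, so no array shows what this probe set reads in a female. Admixture of RNA from a female stays open: *Eif2s3y* was at least 0.32 above the lowest other array in both organs, but a small share of female RNA would dilute it by less than the arrays differ. A second X chromosome in 1 male, the biological candidate explanation, also stays open, since only *Ddx3x* and *Kdm5c* of the escape genes were measured and their median deviation was 0.14 in liver, inside the range of the other livers, and 0.24 in kidney, above it. That both organs came from 1 animal is a hypothesis: 15 of 17 kidney arrays matched best a liver array of their own dose (permutation p = 1e-04, the smallest that 10000 permutations can give; at most 11 in the permutations), which is consistent with shared animals but also with a shared dose or handling, and the pair with *Xist* had a correlation below that of the best other liver array at each size tried, with a difference of −0.00688 over 200 probe sets, −0.0460 over 100 and −0.0576 over 50, all inside the bound of 0.1, which leaves it open.

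An array lay far from the rest of its group in 10 of 181 groups tested, *Xist* included, where chance gives about 9.05. The other 9 follow. Neutrophil markers averaged 4.26 in liver vehicle replicate 2 beside 3.92 to 3.97. Adipose markers averaged 5.91 in liver 10 mg/kg replicate 4 beside 5.64 to 5.68, and adrenal markers 4.40 in liver 10 mg/kg replicate 3 beside 4.22 to 4.25. Thick ascending limb markers averaged 4.78 in liver 500 mg/kg replicate 2 beside 4.44 to 4.46. *Ehhadh* read 11.81 in liver 500 mg/kg replicate 4 beside 11.51 to 11.55, and 11.25 in liver vehicle replicate 1 beside 10.68 to 10.76. *Nqo1* read 7.95 in liver vehicle replicate 1 beside 7.22 to 7.34, *Cdkn1a* 8.15 in liver vehicle replicate 4 beside 7.63 to 7.67, and *Adh1c* 13.15 in liver 500 mg/kg replicate 2 beside 13.55 to 13.59.

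The liver change minus the kidney change at 500 mg/kg passed limma's threshold for 9 probe sets. It was 1.05 for *Hes6*, 1.12 for *Ccdc85c* and 1.04 for *Slc16a13*, and −1.55 for *Trps1*, −1.35 for *Cgnl1* and −1.35 for *Spats2l*, the last 2 of which lie outside the rule for named genes and were chosen after their values were seen. For 3 probe sets with no gene name it was −1.84, −2.04 and −0.97. With kidney vehicle replicate 1 as the only kidney control, a comparison of values with no test, each kept its sign. *Cgnl1* moved to −0.46, *Spats2l* to −0.81 and the unnamed probe sets to −1.02, −1.03 and −0.82, while *Hes6*, *Ccdc85c*, *Slc16a13* and *Trps1* were 0.89, 0.81, 0.97 and −1.11.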

How the results depend on the processing

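The fits added after the data were seen are those with an adipose or GAPDH covariate, those without 2 doubtful kidney arrays (1 mg/kg replicate 1 and 300 mg/kg replicate 2), those without kidney vehicle replicate 1 and with the adipose covariate, the one with only that vehicle array, and the lists with each array left out. Of 291 counts of probe sets under other settings, 204 stayed within 1.5 times the reported count, which includes reported counts of 0 that stayed 0. Comparisons with calls moved more. With 1 array left out the count moved further than that in 8 of 8 fits for liver at 300 mg/kg. It did so in 7 of 8 for liver at 500 mg/kg, 7 of 27 for the liver trend and 11 of 14 for the organ difference at 500 mg/kg. Of 729 refits of named genes past the threshold, 550 stayed past it, 179 did not and 0 changed sign. The 8 genes of the liver trend, with 34 refits each, stayed past it in 33 or 34, so the other comparisons kept a smaller share. Of 190 refits of called lists, 146 stayed past it and 44 did not. All 18 list calls were lost with an estimated correlation, fry kept 6 and the mean of a gene's probe sets kept 17. For lists not called, 51 of 990 refits passed the threshold, and cell cycle genes in kidney at 100 mg/kg passed with the opposite sign without vehicle replicate 1 (adjusted p = 0.00468, and up to 0.983 with another array left out). With only brighter probe sets the counts were 139 at 300 mg/kg in liver, 104 at 500 mg/kg, 211 in the liver trend, and 2 and 70 in the organ difference at 300 and 500 mg/kg; fewer probe sets are tested there. A second quantile normalization lost 6 of 37 named calls and gave 16 at 300 mg/kg in liver, 14 of them among the 38 reported, and 16 in the organ difference at 500 mg/kg; it lowered the share of higher calls from 86.8% to 75.0% at 300 mg/kg, from 67.3% to 56.9% at 500 mg/kg and from 68.4% to 56.1% in the liver trend. With 1 probe set per gene there were 60 at 300 mg/kg in liver. With trend and robust options there were 84, 136 and 167 at 300 mg/kg, at 500 mg/kg and in the trend in liver, and 1 and 26 in the organ difference at 300 and 500 mg/kg. Array weights gave 60 and 84 in liver at 300 and 500 mg/kg, 424 in kidney at 500 mg/kg, and 16 and 951 in the organ difference; the weight of kidney vehicle replicate 1 was 0.593. Fits of only the 2 groups compared, which estimate the spread from fewer arrays, gave 2 and 1 in liver at 300 and 500 mg/kg, and 1 and 1 in kidney at 0.1 and 1 mg/kg, and lost 24 of 25 named calls. Dose in mg/kg as a number gave 361 in the liver trend and 3 in the kidney trend. With the replicate block 8 of 37 named calls were lost, and there were 60 at 300 mg/kg in liver, 50 in the liver trend and 3 in the organ difference at 500 mg/kg; same-numbered arrays deviated together with r = 0.02 in liver and 0.00 in kidney, and the lowest same-numbered pairs had r = −0.14 and −0.35, so the numbers were not taken to pair samples. Even so, 16 of 27 liver arrays correlated best with an array of their own number (permutation p = 0.00220, median 7 when numbers are permuted within doses), a hint from the data of something shared, and 7 of 17 kidney arrays did (permutation p = 0.406, median 6); this check against chance was added after the values were seen. Without kidney vehicle replicate 1 and with the adipose covariate the counts in kidney, in rising order of dose, were 91, 217, 7, 1, 27 and 510. The adipose and the GAPDH covariate alone left limma's count at 0 in each kidney comparison and the kidney trend, and so did vehicle replicate 1 as the only control at 500 mg/kg. Without the 2 doubtful kidney arrays the counts were 6 at 1 mg/kg, and 3 and 41 in the organ difference at 300 and 500 mg/kg. Where no construction is named, the cause was not tested. Leaving out 1 array gave 0 to 1, 0 to 0, 0 to 1, 0 to 2, 0 to 22 and 9 to 84 probe sets in liver from 0.1 to 500 mg/kg and 12 to 91 in the liver trend. In kidney it gave 0 to 319, 0 to 201, 0 to 138, 0 to 23, 0 to 103 and 0 to 616, and 0 to 0 in the trend. In the organ difference it gave 0 to 200 at 300 mg/kg and 0 to 746 at 500 mg/kg. At 2 arrays per group, leaving out 1 leaves a lone array that is assumed to vary like the other groups. Signal over background limits what dim probe sets can show: RMA values near the lower end of the scale compress changes, and no background calls were used here.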

Other observations

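The test of RNA integrity in kidney and the fits added to follow it were chosen after the kidney result was seen, as were the synthetase list, the condition that the pooled low dose value holds with each array left out, and the tests of sampling time and of amino acid transport; the other tests in this part were written before their values were seen.

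Genes of the circadian clock, the feedback loop of transcription factors that times daily rhythms, differed in kidney at 500 mg/kg, where 8 of 16 measured members passed adjusted over the list alone and 0 passed limma's threshold over all probe sets. The repressor *Nr1d1* (−0.98) and *Dbp* (−1.18), an activator of rhythmic output genes, were lower, and *Cry1* (0.76) and *Hlf* (0.75) were higher. The list as a whole was not called in 1 direction (camera adjusted p = 0.677). *Dbp* read 7.18, 7.99 and 9.11 in vehicle kidneys 1 to 3 and between 6.57 and 7.17 at 500 mg/kg, so the highest array at 500 mg/kg lay just below the lowest vehicle array. It read 6.65 to 7.28 at 0.1 and 10 mg/kg, near the values at 500 mg/kg, and 7.51 to 8.46 at 1, 100 and 300 mg/kg. *Nr1d1* read 5.77 or more at 0.1 mg/kg, 5.54 and 5.81 at 10 mg/kg, 6.28 to 6.64 at 1, 100 and 300 mg/kg and at most 5.76 at 500 mg/kg. These readings do not follow the order of the doses, and their cause was not tested. Adjusted over the kidney injury list alone *Gdf15*, a stress cytokine, differed by −1.31 in kidney at 500 mg/kg, and over the glucose list pyruvate carboxylase *Pc* by −0.80; neither passed over all probe sets.

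The direct comparison of 300 with 500 mg/kg in liver passed limma's threshold for 2 probe sets, with 2456 at an unadjusted p under 0.05. *Eci1* (−0.70, SE 0.11) and the thioesterase *Acot2* (−0.59, SE 0.10) were lower at 300 than at 500 mg/kg (adjusted p = 0.0323 for each, 4 arrays per group). Both are in the PPARA list, and *Acot2* was chosen after its values were seen. PPARA targets had a median of −0.18 (camera adjusted p = 4.5e-12; p = 9.9e-04 with an estimated correlation), and fatty acid synthesis genes one of 0.28 (camera adjusted p = 0.00139; p = 0.129 with an estimated correlation). Oxidative phosphorylation (−0.05, camera adjusted p = 9.3e-04; p = 0.137 with an estimated correlation), CAR and PXR targets (−0.10, 0.0391; p = 0.101) and heat shock genes (−0.10, 0.0445; p = 0.142) completed the 5 of 20 lists that passed. *Slc3a2* differed by 0.58 (adjusted p = 0.157) and *Asns* by 1.18 (0.22).

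Cytosolic aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, had 0, 6 and 0 of 19 measured members past limma's threshold at 100, 300 and 500 mg/kg in liver and 10, 15 and 3 higher adjusted over the list alone, with medians of 0.22, 0.30 and 0.17 and a median difference between 300 and 500 mg/kg of 0.19 (camera p = 7.1e-09; p = 0.0229 with an estimated correlation); the list was chosen from the calls at 300 mg/kg and is not independent evidence of its direction. Against the 11 arrays at 0.1, 1 and 10 mg/kg the median of the synthetases was 0.27 (0.23 to 0.29 with 1 array left out). The 300 mg/kg arrays thus lay above the low doses as well as above vehicle. The list was chosen from calls in the same 300 mg/kg arrays, which favours high values there. Low values of the vehicle arrays as the whole cause are therefore not excluded. Low vehicle values also stay open for the amino acid transport genes *Slc3a2*, *Slc7a1* and *Slc6a9*, chosen after their values were seen. Their median went from 0.82 against vehicle to 0.44 against the low dose arrays (0.36 to 0.53 with 1 array left out). With each 300 mg/kg array left out the median of the synthetases was at least 0.26. Since the list was chosen from calls in these same arrays, a stable median was likely and does not decide dependence on 1 array. A different sampling time stays open: limma's fry, testing the liver clock list for change in either direction between 300 and 500 mg/kg, gave 0.304 as its p, the interval of *Nr1d1* runs from −0.56 to 1.82, and in kidney *Nr1d1* differed by 0.95 between these doses (0.0146 adjusted over the list alone); a biological cause was not tested.

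The absence of calls in kidney could have technical causes. Fat in some kidney pieces as the whole cause is argued against by 0 calls at 500 mg/kg with the adipose covariate. That covariate was past limma's threshold for 32 probe sets but took the median residual SD only from 0.156 to 0.152. Degraded or liver RNA in 2 arrays (1 mg/kg replicate 1 and 300 mg/kg replicate 2) stays open. Without them there were 0 calls at 500 mg/kg, but that comparison holds neither array. Only their part in the shared spread was tested there. Too few arrays stays open. Of simulated changes of 1 log2 unit, 83.6% were recovered at 500 mg/kg (exact binomial 95% interval 72.5% to 91.5%, 56 of 67). At 300 mg/kg, with as many arrays per group, 97.0% were (65 of 67), so the share depends on the simulated draw. Of simulated changes of 0.5, 43.3% were recovered at 500 mg/kg and 38.8% at 300 mg/kg, and 9 of the 55 liver calls at 500 mg/kg reached 1 log2 unit. Lower RNA integrity in vehicle replicates 2 and 3 stays open. Their GAPDH 3' minus 5' differences were 0.57 and 0.60, beside 0.31 in vehicle replicate 1. They lay little above 100 mg/kg replicate 1, at 0.55, and the kidney median was 0.45. Without vehicle replicate 1, 495 probe sets were higher at 500 mg/kg. The array with the largest GAPDH difference, 300 mg/kg replicate 2, lay below its group in 87.7% of them, with a median difference of −0.31. Over the same probe sets 1 mg/kg replicate 2 differed from replicate 1 by a median of −0.21, although both had a GAPDH difference of 0.48. A real difference between kidneys was not tested.

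Splits of the same arrays into other groups of equal size were counted for each comparison. Chance is argued against for liver at 300 mg/kg, where 1 of 35 splits, the real one, gave 38 probe sets and the highest other gave 1. Even so, 0 remain without vehicle replicate 2, the array with *Xist*. It is argued against at 500 mg/kg, where 1 of 35 gave 55 and the highest other 13. In the liver trend, where 1 of 100 gave 76 and the highest other 2, it is also argued against. A share of 1 of 35 is the smallest that 35 splits can give, and the shares were not adjusted over the comparisons. For the organ difference at 500 mg/kg, 2 of 100 splits gave 9 or more. The highest other gave 13, more than the real one. In that split the kidney arrays keep their real groups with the labels exchanged, so its 13 does not measure chance alone. Chance is still not excluded for the organ difference. Its 9 become 746, 0 and 2 without kidney vehicle replicates 1 to 3 in turn. Where the real count is 0 every split reaches it by construction, so the count of splits tests nothing and chance is not excluded. That holds at 0.1, 1, 10 and 100 mg/kg in liver (35 of 35 splits, highest others 1, 1, 1 and 0), in the kidney trend (100 of 100, highest other 42) and in the organ difference at 300 mg/kg (100 of 100, highest other 1133). In kidney the 10 splits of 3 against 3 arrays are too few to give a share under 0.05, with 0 real calls and a highest other of 1422 at 300 mg/kg, and 0 and 2 at 500 mg/kg; all 10 reached 0. The split with 1422 sets vehicle replicates 2 and 3 and 300 mg/kg replicate 2 against the rest, which points to a structure of the samples.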
